A study of Mus musculus with 10 samples.

How the data were processed

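The labels describe primary mouse embryonic fibroblasts, starved for 48 h and then given 10% or 1% fetal bovine serum for 2 h. Per the labels' protocols, gradient cultures received cycloheximide, which halts ribosomes, for 30 min before lysis and cytoplasmic cultures did not. RNA was reverse-transcribed, amplified linearly, labelled with biotin and hybridized to Affymetrix arrays, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 per probe set and array. The method that summarised probes to probe sets and any scaling by the authors are not given in the sources used here. Nuclear RNA was not analysed here.

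The table holds 12488 probe sets, 66 of them controls. Of the other 12422, 10833 have 1 gene symbol in the platform annotation given for this work, 396 have several and 1193 have none there. The Entrez gene of 10817 matched the reference gene table and no symbol changed. Genes were named only from probe sets with 1 symbol. Of 14 genes to be reported in any case, Gapdh and Atf1 had no ordinary probe set named for them here. The level of the disrupted gene could therefore not be checked.

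Values were taken as log2(value + 1.5), the pseudocount being the 10th percentile of all values, which shrinks fold changes of dim genes before scaling. Array medians differed by up to 2.953 log2 units, over the limit of 0.25 set beforehand, so arrays were quantile normalized over all 10. This gives dim and bright arrays the same distribution, so fold changes of dim genes between pools may be over- or understated after it. Probe sets at or below the 25th percentile of mean level were left out, which left 9316. limma 3.58.1 in R 4.3.3 fitted the 4 gradient groups (8 arrays, 4 residual degrees of freedom) with lmFit and eBayes with a trend. All tests were two-sided, with Benjamini-Hochberg adjustment at 0.05 within each comparison. Contrasts were the serum response averaged over and within the fractions, polyribosome against undertranslated RNA averaged over and within the serum states, their interaction, and replicate 2 against replicate 1.

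Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, for lists with at least 5 measured genes and 1 probe set per gene, 22 lists in the 8-array model. An estimated correlation is given beside it. Cell type marker lists were tested the same way. For the cytoplasmic pair, list medians were set among 10000 random lists matched on level in 20 bins. The design, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest rises and falls of the main comparisons among probe sets that passed and had the same direction in all pairs, up to 4 called members of each list, and 14 fixed genes. For single-fraction contrasts it takes 3 each way, for the replicate contrast 5, and for the cytoplasmic pair 10. Of these the text prints a part in order of size: for the lists of the averaged fraction difference the 2 largest called members, a number set after the values were seen. For a gene with several probe sets the one with the highest mean level is given, with others where they differ. The fit over 6 polyribosome and cytoplasmic arrays was added after the data were seen, and its genes follow the same rule.

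Background was the highest of 19 bacterial and yeast control probe sets that were not spiked in, taken on each array. Where a probe set was above it on no array of 1 side, the fold is a bound: the bright side's mean against the mean of, per array, the higher of the lowest level above background and the probe set's own level. Such a bound is taken on the scaled values and holds within the main scaling only.

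Replicate numbers come from the labels, and number 2 marks 4-thiouridine labelling in every gradient group, so the numbers pair arrays by that treatment. Deviations of same-numbered arrays from their group means correlated at 0.271 between the polyribosome groups and at 0.0136 to 0.0532 between the other groups. The replicate block was an alternative fit. Other alternatives set beforehand were the values as deposited, median centring, pseudocounts of 1 and 4.2, no filter and a filter at the 50th percentile, no variance trend, 1 probe set per gene, all 10 arrays, and each array left out. Scaling by 9 hybridization control probe sets, array weights and a restriction to probe sets above background on all 8 arrays were added after the data were seen.

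The fits were tested on simulated data with 200 changed probe sets among 9316, drawn from the real means and spreads. The cytoplasmic pool has no replicate, so its spread was taken from the polyribosome arrays. Where a serum fit covered 2 pools, the change was the same in both. Recovery in the fit over polyribosome and cytoplasmic RNA rests on these assumptions. The real averaged fraction difference called 5047 probe sets, far more than were changed here. For a log2 change of 2, 32.5% were recovered for the averaged serum response, 8.82% for serum in polyribosomes, 17.2% for serum in undertranslated RNA, 43.5% for the averaged fraction difference and 83.1% for the fit over polyribosome and cytoplasmic RNA. For a log2 change of 1 the shares were 5.98%, 0%, 3.54%, 9.26% and 27%. False calls numbered 3, 0, 28, 8 and 3 in the same order.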

Results

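The arrays profiled mRNA of primary mouse embryonic fibroblasts carrying 1 disrupted copy of Atf1, per the labels' genotype. The series asks how the mRNA pool and its translation respond early to serum. All cultures were starved for 48 h in 1% fetal bovine serum and then kept for 2 h in 10% serum (serum-treated) or in 1% serum (starved). RNA came from 3 pools. Cytoplasmic RNA was taken from cells without cycloheximide. Undertranslated RNA was the part of a sucrose gradient with no ribosome, a ribosomal subunit or 1 ribosome, and polyribosome-associated RNA was the part with more ribosomes per mRNA. The 10 arrays fall into 6 groups, with 1 array in each cytoplasmic group and 2 arrays in each gradient group. Replicate 2 of each gradient group came from cultures labelled with 3H-cytidine and with 4-thiouridine at 200 uM, a nucleoside that marks new RNA. Replicate 1 received neither. Gradient fractions of several cultures were pooled before hybridization, so p-values measure the spread between pools, which may be partly technical. Undertranslated and polyribosome RNA are parts of a gradient, so same-numbered arrays of a serum state may come from the same cultures. No fit had a term for this, and arrays averaged or compared over the fractions may not be independent.

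The undertranslated arrays were dim. Their median intensity was 5.7 to 8.8, against 45.3 to 54.2 on the polyribosome arrays and 19.1 to 19.2 on the cytoplasmic arrays. Between 43.4% and 53.5% of probe sets lay above background on the undertranslated arrays, 68% to 73.5% on the polyribosome arrays and 56.3% to 64.7% on the cytoplasmic arrays. Replicate log2 values correlated across probe sets at r = 0.969 in both polyribosome groups, at 0.887 in starved undertranslated RNA and at 0.789 in serum-treated undertranslated RNA. The median SD between replicates was 0.20 log2 units in both polyribosome groups, 0.34 in starved and 0.57 in serum-treated undertranslated RNA. The number of arrays limits the precision of each comparison.

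**Figure D1:**
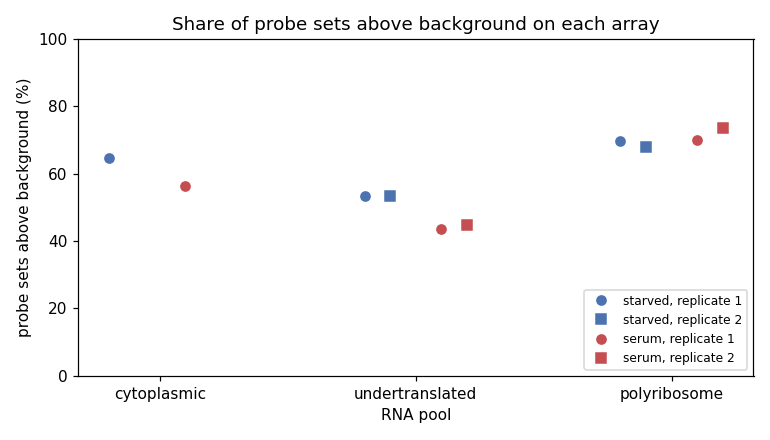
Percent of probe sets above background (y axis, from 0 to 100) on each of the 10 arrays, by RNA pool (x axis); colour gives the serum state and marker shape the replicate. The 4 undertranslated arrays lie between 43.4% and 53.5%, below the 4 polyribosome arrays at 68% to 73.5%.

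The first comparison asked which mRNAs change with serum when both gradient fractions are averaged. Secreted and extracellular early-response factors lay higher after serum as a group, with a median log2 difference of 0.52 over 23 genes. Signalling feedback regulators were shifted the same way, with a median of 0.27 over 21 genes. Starvation and FoxO-linked genes lay lower, with a median of -0.35 over 20 genes, as did p53 target genes at -0.39 over 14 genes and proteasome subunits at -0.37 over 36 genes. Camera gave adjusted p-values of 0.000525 for the secreted factors, 0.0188 each for the feedback, starvation and p53 lists, and 0.0475 for the proteasome. None of these calls held when the correlation between genes was estimated, where the lowest adjusted p was 0.516 with an estimated correlation. Adjusted over the list alone, 6 secreted factors rose, 3 feedback regulators rose and 1 fell, 7 starvation genes fell, 3 p53 targets fell and no proteasome gene passed. Macrophage markers moved with these groups, with a median of 1.20 over 9 genes (camera adjusted p = 3.33e-05, and adjusted p = 0.0744 with an estimated correlation). Endothelial markers, with a median of 0.94 over 7 genes, and epithelial markers, with 0.79 over 5 genes, did so too (camera adjusted p = 0.00838 each, and adjusted p = 0.0744 each with an estimated correlation). The p53 and proteasome lists were not called in the fit over polyribosome and cytoplasmic RNA described below. In the cytoplasmic pair their medians were -0.05 and -0.12, at percentiles 36.36 and 10.6 of random lists matched on level. The 5 list calls became 1 without serum undertranslated replicate 1, 2 without any other undertranslated array or without starved polyribosome replicate 2, and 3 without serum polyribosome replicate 1.

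No single probe set of the 9316 tested passed in this average. limma gave 1074 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0725. Immediate-early genes that serum classically induces had differences near 0 at 2 h, the only time measured: Fos -0.20 ± 0.22 (SE, 4 arrays per side), Egr1 0.003 ± 0.25 and Dusp1 0.006 ± 0.16. Fos and Egr1 were already high in starved cells, with log2 levels of 11.09 and 10.90 in undertranslated and 10.67 and 11.38 in polyribosome RNA. An earlier rise was not measured. Ptgs2, the inducible cyclooxygenase, stood at 0.52 ± 0.19 (adjusted p = 0.34) and Odc1, an enzyme of polyamine synthesis, at 0.65 ± 0.20 (adjusted p = 0.272). Junb stood at -0.14 ± 0.40, Myc at 0.23 ± 0.38 (above background on 3 of 4 undertranslated arrays), Ccl2 at 0.068 ± 0.12, Atf4 at -0.13 ± 0.21, Actb at 0.42 ± 0.19, Fth1 at 0.034 ± 0.16 and Eef1a1 at -0.22 ± 0.07, none of them past the test. Without serum undertranslated replicate 1 the count became 117, and without serum undertranslated replicate 2 it became 1243. Under other scalings it was 6 with values as deposited, 27 with median centring and 42 with hybridization control scaling, and Egr1, Ccl2, Fth1, Dusp1, Actb and Ptgs2 changed sign under at least one of these.

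A second look at the serum response used the brighter arrays alone, a choice made after the data were seen: 3 serum-treated arrays (2 polyribosome, 1 cytoplasmic) against 3 starved ones, with the RNA pool as a factor. Serum raised 65 probe sets and lowered 21 of 9316, from 51 and 19 genes. The largest rises were Sema7a, a membrane-anchored semaphorin, by 2.95 ± 0.26 log2 units (SE; adjusted p = 0.0033; above background on 2 of 3 starved arrays), and Serpinb2, an inhibitor of plasminogen activators, by 2.78 ± 0.19 (adjusted p = 0.000804). The cytokine Il11 rose at least 4.68-fold, since its probe set was below background on the 3 starved arrays. Falls were led by the transcription factor Snai2 at -1.82 ± 0.23, the interleukin 1 receptor antagonist Il1rn at -1.80 ± 0.21 and the pyruvate dehydrogenase kinase Pdk4 at -1.75 ± 0.20 (above background on 2 of 3 serum-treated arrays). All 86 differences had the same sign in the cytoplasmic pair and in the polyribosome means, which both entered the fit, and 73 had it in undertranslated RNA, which did not. The undertranslated arrays may come from the same cultures as the polyribosome arrays, so this is not an independent check. The share of same signs over all probe sets was not computed.

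Of 25 measured secreted and extracellular early-response factors 9 rose and none fell (14 rose and 1 fell adjusted over the list alone). They included Vegfa at 1.91 ± 0.29 (above background on 1 of 3 starved arrays), the activin subunit Inhba at 1.89 ± 0.22 and the urokinase receptor Plaur at 1.73 ± 0.25, and the list's camera adjusted p was 9.99e-11 (adjusted p = 0.104 with an estimated correlation). Further large rises were Srxn1, which repairs oxidised peroxiredoxins, at 2.10 ± 0.22, the gap junction gene Gjb2 at 2.07 ± 0.24, Fgl2 at 2.05 ± 0.21 (above background on 2 of 3 starved arrays), the somatostatin receptor Sstr2 at 1.98 ± 0.25 and the lectin Clec4d at 1.77 ± 0.25. Il1b was at least 2.11-fold higher and Plet1 at least 1.83-fold higher. Macrophage markers rose in the same fit, as given below, and which cells of the cultures the rises listed here came from was not tested. Timp1, an inhibitor of matrix metalloproteinases, rose by 1.51 ± 0.21. Other probe sets of some of these genes did not pass: a second Sema7a probe set stood at 0.14 ± 0.40, one of Srxn1 at -0.26 ± 0.25, and those of Sstr2 at 1.12 ± 0.29 and 1.15 ± 0.39.

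Among 20 immediate-early transcription factors, Cebpb rose by 1.37 ± 0.23 and Fosl1 by 1.25 ± 0.20, while 18 did not pass. Fos stood at -0.21 ± 0.20, Egr1 at -0.045 ± 0.29, Junb at 0.74 ± 0.20 (adjusted p = 0.174) and Myc at 0.69 ± 0.23 (adjusted p = 0.264). Of 21 feedback regulators Gadd45b rose by 1.42 ± 0.20 and Rgs16 by 1.08 ± 0.20. Adjusted over the list alone, 5 immediate-early genes rose and 1 fell, and 7 feedback regulators rose and 1 fell. Camera adjusted p-values were 0.00819 for the immediate-early list and 1.54e-05 for the feedback list, and both had an adjusted p of 0.303 with an estimated correlation. Other always reported genes did not pass: Ptgs2 stood at 0.76 ± 0.18, Odc1 at 0.80 ± 0.18, Dusp1 at 0.12 ± 0.19, Ccl2 at 0.097 ± 0.16, Atf4 at -0.26 ± 0.18, Actb at 0.18 ± 0.19, Fth1 at -0.023 ± 0.20 and Eef1a1 at 0 ± 0.13.

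Of 20 measured starvation and FoxO-linked genes, 3 fell, none rose and 17 did not pass: Pdk4, the growth arrest gene Gas1 at -1.69 ± 0.20 and Ccng2, an atypical cyclin, at -1.58 ± 0.26. Adjusted over the list alone 12 fell, and the camera adjusted p was 1.12e-06 (adjusted p = 0.303 with an estimated correlation). The aryl hydrocarbon receptor Ahr fell by 1.57 ± 0.26, Bmp4 by 1.57 ± 0.24, Pag1 by 1.45 ± 0.22, 1600012H06Rik by 1.42 ± 0.25, Rab9 by 1.39 ± 0.20 and the Wnt agonist Rspo2 by 1.36 ± 0.21. Ahr and 1600012H06Rik were above background on 2 of 3 serum-treated arrays. Map3k11 was at least 1.67-fold lower. No single cholesterol synthesis gene of 16 passed (1 rose adjusted over the list alone), while 15 lay above 0 with a median of 0.46 (camera adjusted p = 2e-05, and adjusted p = 0.21 with an estimated correlation). Actin and SRF target genes had a median of 0.18 over 23 genes (camera adjusted p = 0.00819, and adjusted p = 0.303 with an estimated correlation), with none past the test adjusted over the list alone. Ribosome biogenesis genes had a median of 0.22 over 26 genes (camera adjusted p = 0.00969, and adjusted p = 0.353 with an estimated correlation), and 2 rose adjusted over the list alone.

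**Figure D2:**
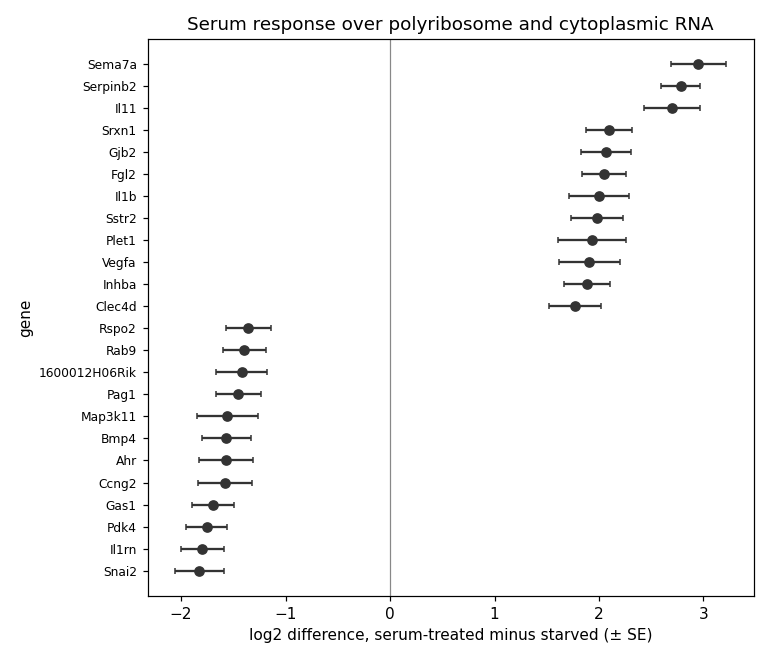
Log2 difference between serum-treated and starved cells (x axis, with SE bars) for the 12 largest rises and 12 largest falls (y axis) over 6 polyribosome and cytoplasmic arrays. Sema7a lies at 2.95 and Snai2 at -1.82; values of Il11, Il1b, Plet1 and Map3k11 are fitted ones for which only a bound is measured.

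Of 9 measured macrophage markers, 6 rose beside these genes and none fell (8 rose adjusted over the list alone), among them the cathepsin Ctss by 1.74 ± 0.17, lysozyme Lyz2 by 1.67 ± 0.26, Tyrobp by 1.43 ± 0.24 and Laptm5 by 1.41 ± 0.25, while a second Lyz2 probe set stood at 0.21 ± 0.25. The list's median was 1.27 (camera adjusted p = 7.57e-13, and adjusted p = 0.107 with an estimated correlation). Epithelial markers had a median of 0.44 over 6 genes, with no gene past the test over all probe sets and 2 risen adjusted over the list alone (camera adjusted p = 0.00158, and adjusted p = 0.107 with an estimated correlation).

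The number of serum-responsive probe sets depended on single arrays. It was 86 with all 6 arrays, 5 without the starved cytoplasmic array, 5 without the serum cytoplasmic array, 18 without serum polyribosome replicate 2, 21 without starved polyribosome replicate 1 and 142 without starved polyribosome replicate 2. Leaving out either cytoplasmic array gives the same serum estimate, from the polyribosome arrays alone, because the pool factor takes up the remaining one. These omissions are therefore not separate checks. The number was 155 with the replicate block, of which 85 were among the 86. The share of rises among calls was 75.6%, 62.3% with values as deposited and 28.8% with hybridization control scaling, which moved the median of all probe sets to -0.39.

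**Figure D3:**
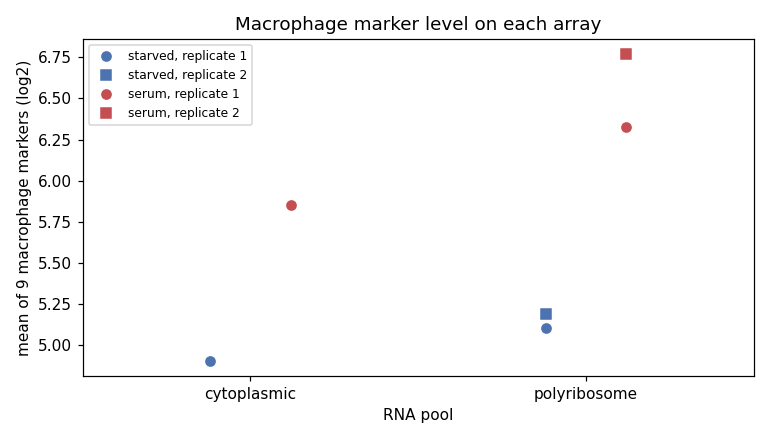
Mean log2 level of 9 macrophage markers (y axis) on each cytoplasmic and polyribosome array (x axis); colour gives the serum state and marker shape the replicate. The 3 serum-treated arrays lie between 5.85 and 6.77, and the 3 starved arrays between 4.91 and 5.19.

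The serum response was then taken within each gradient fraction. In polyribosome-associated RNA no probe set passed in the 8-array model (158 at an unadjusted p under 0.05 with limma). That model shares 1 estimate of the spread with the undertranslated arrays, whose median replicate SD was 0.34 and 0.57 against 0.20 in both polyribosome groups. It recovered 8.82% of simulated log2 changes of 2 in polyribosomes, so the absence of calls says little. With the 4 polyribosome arrays fitted alone, added after the data were seen, 6 probe sets rose and none fell (584 at an unadjusted p under 0.05). They were Sema7a, Serpinb2, Fgl2, Rasd1, the macrophage marker Laptm5 and 1 probe set with no symbol, named after their values were seen. That fit with the replicate block gave 120 rises and 57 falls on 1 residual degree of freedom.

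In undertranslated RNA 27 probe sets rose and 73 fell with serum. Foxn3, a forkhead factor, was at least 6.08-fold higher, the VEGF receptor Flt1 at least 5.78-fold and Mup3 at least 3.09-fold. Anapc4, a subunit of the anaphase-promoting complex, was at least 4.91-fold lower, Znhit1 at least 1.85-fold lower, and Il1rn fell by 4.02 ± 0.74 log2 units (adjusted p = 0.0476; above background on 1 of 2 serum-treated arrays). The replicate block left 8 rises and 46 falls. Leaving out either starved undertranslated array or any 1 polyribosome array gave 0, and leaving out serum undertranslated replicate 1 or replicate 2 gave 433 or 2292. On simulated data of this comparison 28 calls were false, beside 4 true ones at a log2 change of 1 and 15 at a change of 2, so false calls exceeded the share the threshold allows. Rises made up 27% of the calls, 10.3% with median centring and none of the 22 calls with values as deposited. The ratio of 3' to 5' control probe sets, a sign of RNA quality, differed between the states in this pool. For Actb it was 137 and 61.4 on the starved and 23.6 and 33.9 on the serum-treated arrays, and for Gapdh 5.64 and 6.81 against 3.70 and 4.53.

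No gene passed the test for a change of the split between the fractions with serum. The interaction term gave 0 of 9316 probe sets (721 at an unadjusted p under 0.05 with limma). Its recovery was not simulated. The averaged serum response of the same model recovered 32.5% of simulated log2 changes of 2, so the absence of calls here says little. Secreted early-response factors had the lowest list p-value, with a median of 0.58 over 23 genes toward polyribosomes after serum, which did not pass (camera adjusted p = 0.109, and adjusted p = 0.904 with an estimated correlation). No list passed, against 11 with values as deposited, 12 with median centring and 11 with hybridization control scaling. Junb stood at 1.48 ± 0.79 (adjusted p = 0.701), Myc at 1.35 ± 0.75 (0.712), Ptgs2 at 0.63 ± 0.38 (0.713) and Eef1a1 at 0.45 ± 0.14 (0.563). Fos stood at 0.13 ± 0.44, Egr1 at 0.03 ± 0.50, Ccl2 at 0.13 ± 0.25, Odc1 at 0.027 ± 0.40, Actb at -0.48 ± 0.37, Atf4 at -0.36 ± 0.42, Dusp1 at -0.095 ± 0.32 and Fth1 at -0.05 ± 0.32. Without serum undertranslated replicate 2 the count was 900 and without serum undertranslated replicate 1 it was 2.

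The next comparison set polyribosome-associated against undertranslated RNA over both serum states. Values are relative to the distribution of each array, because the main scaling gives all arrays the same distribution. The bounds below hold within that scaling only. With values as deposited the median probe set stood 3.02 log2 units toward polyribosomes, so folds toward undertranslated RNA need not reach them there. Among the largest differences toward polyribosomes, Serpinf1, a secreted serpin, was at least 28.2-fold higher there, the disulfide isomerase family member Txndc5 at least 17.6-fold, and the collagen chaperone Serpinh1 was higher by 5.41 ± 0.36 log2 units (adjusted p = 2.76e-05; above background on 2 of 4 undertranslated arrays). The proteasome subunit Psmd4 was at least 14.5-fold higher, Capns1 at least 11.1-fold, Tspan4 at least 8.58-fold, the lysosomal carboxypeptidase Ctsa at least 8.43-fold, Samm50 at least 5.36-fold, Lclat1 by 5.18 ± 0.57 log2 units, the histidyl-tRNA synthetase Hars at least 5.12-fold, the sphingosine kinase Sphk1 at least 4.77-fold and Rabac1 by 5.02 ± 0.60 log2 units. Lclat1 and Rabac1 were above background on 1 of 4 undertranslated arrays. Toward undertranslated RNA lay the probe sets of Sgip1, at least 35.2-fold, Gm15987, at least 8.12-fold, and the ribosomal protein mRNA Rpl32, at least 6.37-fold. They were above background on none of the polyribosome arrays, and how well they measure their mRNAs was not tested.

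In all, 2629 probe sets were higher in polyribosomes and 2418 lower, of 9316. Called falls also included the Polycomb gene Pcgf2 at -3.67 ± 0.40, Nmur1 at -3.80 ± 0.35, 1110032A03Rik at -3.69 ± 0.32, A530040E14Rik at -3.61 ± 0.35, Akap1 at -3.60 ± 0.44, Usp25 at -3.58 ± 0.44, Vps13c at -3.58 ± 0.39 and Syne4 at -3.58 ± 0.30. Nmur1 and Akap1 were above background on 1 of 4 polyribosome arrays, and A530040E14Rik, Usp25 and Vps13c on 3 of 4. The probe sets of some genes differed in sign: Col1a1 stood at -3.65 ± 0.22 on one and 0.57 ± 0.19 on another, Meg3 at -1.47 ± 0.34 and 3.56 ± 0.45, Akap1 at 2.09 ± 0.55 and Serpinf1 at -0.85 ± 0.54 on their other ones, and 144 of 1270 genes with several tested probe sets had calls both ways. Of the higher calls 748 were below background on all 4 undertranslated arrays, and of the lower ones 207 were below background on all 4 polyribosome arrays.

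Extracellular matrix genes lay toward polyribosomes, with 18 of 27 higher and 2 lower (19 and 2 adjusted over the list alone), the largest by size being Serpinh1 and, on 1 of its probe sets, Col1a1 in the other direction. Proteasome subunits followed with 20 of 36 higher and 4 lower (21 and 4 adjusted over the list alone), such as Psmd13 at 4.92 ± 0.40. DNA replication genes had 10 of 21 higher and 1 lower (10 and 1 adjusted over the list alone), including the ribonucleotide reductase subunit Rrm1 at 3.75 ± 0.48. Interferon-stimulated genes had 8 of 14 higher and none lower (8 and 0 adjusted over the list alone), with Gbp2 at least 4.6-fold and Ifi35 at least 3.99-fold higher. p53 target genes had 9 of 14 higher and 1 lower (11 and 1 adjusted over the list alone), such as Rrm2b at 3.00 ± 0.38. Psmd13, Rrm1 and Rrm2b were above background on 1 of 4 undertranslated arrays. Camera adjusted p-values were 0.017 for the matrix and proteasome lists and 0.0302 for the other lists named here, and none held with an estimated correlation (lowest adjusted p = 0.73 with an estimated correlation).

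Ribosomal protein mRNAs went both ways, 10 of 32 higher and 11 lower (the same counts adjusted over the list alone; camera adjusted p = 0.598, and adjusted p = 0.814 with an estimated correlation), with Rpl8 at 4.23 ± 0.33 and Rpl32 as above. Oxidative phosphorylation genes did so too, 22 of 69 higher and 21 lower, as adjusted over the list alone. Of 16 further mRNAs with a 5' terminal oligopyrimidine tract 8 were higher and 4 lower, as adjusted over the list alone. Among growth-response genes, Ptgs2 was higher in polyribosomes by 1.55 ± 0.19 (adjusted p = 0.000292), Dusp6 by 4.27 ± 0.32 (above background on 3 of 4 undertranslated arrays) and Ccn1 by 3.16 ± 0.24. Odc1 was lower at -0.76 ± 0.20 (adjusted p = 0.013), Atf4 at -0.68 ± 0.21 (adjusted p = 0.0234) and Ccl2 at -0.58 ± 0.12 (adjusted p = 0.00457), and all 3 turned positive under each other scaling. Eef1a1 was higher by 0.34 ± 0.07 and turned negative with median centring. Myc, Egr1 and Dusp1 did not pass. Nor did the brightest probe sets of Fos, Junb, Actb and Fth1, whose other probe sets passed at -1.44 ± 0.42, 2.35 ± 0.42, -3.77 ± 0.38 and -3.04 ± 0.29.

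Directions in this comparison rest on the scaling. Higher calls made up 52.1% in the main scaling, 66.5% with median centring, 99.6% with values as deposited and 99.7% with hybridization control scaling, where the median probe set stood at 0.017, 0.55, 3.02 and 3.33 log2 units. Of the 12 largest falls, all named above, 1110032A03Rik, Col1a1, Usp25 and Syne4 turned positive with hybridization control scaling. So did Odc1, Atf4, Ccl2 and the Meg3 probe set at -1.47. The 3' to 5' ratio of Actb was 23.6 to 137 on the undertranslated and 11.5 to 21.1 on the polyribosome arrays, and that of Gapdh 3.70 to 6.81 and 6.11 to 20.9.

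Taken within starved cells, 1335 probe sets were higher in polyribosomes and 1292 lower. Within serum-treated cells 2154 were higher and 1932 lower. The bounds that follow hold within the main scaling only. Psmd4 was at least 17.1-fold higher in starved and at least 12.2-fold higher in serum-treated cells, and Sgip1 at least 22.7-fold and 54.6-fold lower. In starved cells Lclat1 was at least 14.8-fold and Tspan4 at least 11.1-fold higher, and Gm15987 at least 7.4-fold and Uox, urate oxidase, at least 5.79-fold lower. In serum-treated cells Serpinh1 was at least 28.9-fold and Txndc5 at least 13.7-fold higher, and Rpl32 at least 12-fold lower, with 1110032A03Rik at -4.43 ± 0.46. The states shared 1103 higher and 1088 lower calls, and both lists rest on variances estimated from all 8 arrays. The starved count of 2627 became 999 or 706 without starved polyribosome replicate 1 or 2, 1225 without starved undertranslated replicate 1, and 4258 or 4256 without serum undertranslated replicate 1 or 2. The serum-treated count of 4086 became 2070 or 1807 without serum polyribosome replicate 1 or 2. Higher calls made up 50.8% and 52.7% in the states, 71.1% and 71.8% with median centring, and 99.6% in both with values as deposited.

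Cytoplasmic RNA gave 1 array per state, so no p-value can be given. Of 6211 probe sets above the median level, 204 were at least 2-fold higher with serum and 211 at least 2-fold lower. The highest log2 ratios were Sema7a at 3.62 and Serpinb2 at 2.85, followed by Srxn1, Sphk1, Rangap1, Aldh1a3, Tgfb1, Sstr2, Gjb2 and Prp2 at 2.59 to 2.32. The lowest were Bmp4 at -2.29 and Slc6a2 at -2.28, followed by Ahr, 1600012H06Rik, Pdk4, Dipk2a, Ogn, Entpd2, Ccng2 and Gas1 at -2.25 to -1.96. Secreted early-response factors had a median of 0.68, at the 100th percentile of 10000 random lists matched on level, and starvation genes of -0.79, at percentile 0. Ribosome biogenesis genes stood at 0.34 (percentile 99.92), cholesterol synthesis genes at 0.33 (98.84) and feedback regulators at 0.28 (99.18). Macrophage markers had a median of 0.96 (percentile 100), endothelial markers of 0.83 (99.83), epithelial markers of 0.95 over 5 genes (99.63), erythroid markers of 0.78 (99.18) and skeletal muscle markers of 0.12 (71.46). Values as deposited gave 202 higher and 386 lower, and hybridization control scaling 133 and 614. The 3' to 5' ratio of Gapdh was 47.0 on the starved and 28.4 on the serum-treated array, and that of Actb 16.7 and 11.9.

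Replicate 2, from cultures labelled with 4-thiouridine and 3H-cytidine, was last set against replicate 1 within the 4 gradient groups. No gene passed (601 probe sets at an unadjusted p under 0.05 with limma). As groups, proteasome subunits (median 0.30 over 36 genes) and oxidative phosphorylation genes (0.23 over 69) lay higher in replicate 2, each at a camera adjusted p of 0.00565. So did integrated stress response genes (0.31 over 20, adjusted p = 0.0152), matrix genes (0.26 over 27) and ribosomal proteins (0.22 over 32), the last pair at 0.0168. None held with an estimated correlation (adjusted p = 0.513 with an estimated correlation), and no member passed adjusted over the list alone. The 5 list calls became 3 without any 1 serum-treated array, 4 without either starved polyribosome array and 7 without either starved undertranslated array. In polyribosome RNA the 3' to 5' ratio of Gapdh was 14.4 and 20.9 in replicate 1 and 6.24 and 6.11 in replicate 2, and that of Actb 13.4 and 21.1 against 11.5 and 12.8. In undertranslated RNA the Gapdh ratio was 5.64 and 3.70 in replicate 1 and 6.81 and 4.53 in replicate 2, and that of Actb 137 and 23.6 against 61.4 and 33.9. The labelling with either compound and the replicate number cannot be told apart in this design.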

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

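Control probe sets outside the comparisons carried signal above background on all 10 arrays. The B2 repeat, a short interspersed element, had a lowest intensity of 3217.8 over the arrays. It ranged from 5669.4 to 8939.2 in undertranslated RNA and from 7204.3 to 9200.9 in polyribosomes, a ratio of means of 0.874. The B1 repeat had a lowest intensity of 398.3 and a ratio of 0.354, and the middle 18S rRNA probe set a lowest intensity of 30.3 and a ratio of 0.423. The 3' Gapdh control probe set had a ratio of 0.0266, from 68.5 to 180.8 in undertranslated RNA and 4023.9 to 5631.6 in polyribosomes. These are unscaled intensities.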

How the results depend on the processing

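Array weights, hybridization control scaling, the restriction to probe sets above background and everything on the fit over polyribosome and cytoplasmic RNA were chosen after the data were seen. Signal over background limits single values: of 2629 probe sets called higher in polyribosomes, 748 were below background on all 4 undertranslated arrays and have only a bound there. For each change below the cause was not tested, except that fewer arrays or probe sets enter some fits. The averaged serum response called 0 probe sets, and 6 with values as deposited, 27 with arrays centred on their medians, 42 with hybridization control scaling, 3 with array weights, 33 among probe sets above background on all 8 arrays, and 0 to 1243 with single arrays left out. Serum in polyribosomes called 0, and 5 with median centring, 40 with array weights, 6 with the polyribosome arrays only and 177 with those and the replicate block. Serum in undertranslated RNA called 100, and 54 with the replicate block, 22 with values as deposited, 20 with hybridization control scaling, 0 with array weights, 32 among probe sets above background, and 0 to 2292 with single arrays left out. The averaged fraction difference called 5047, and 8559 with values as deposited, 8858 with hybridization control scaling and 2620 among probe sets above background. In starved cells it was 2627, and 7983, 4554 and 8623 with values as deposited, median centring and hybridization control scaling, and 706 to 4258 with single arrays left out. In serum-treated cells it was 4086, and 8008 with values as deposited, 8156 with hybridization control scaling, 2273 among probe sets above background, and 1807 to 5213 with single arrays left out. The interaction called 0, and 0 to 900 with single arrays left out. The serum response over polyribosome and cytoplasmic RNA called 86, and 155 with the replicate block, 24 with no filter, 19 without the variance trend, and 5 to 142 with single arrays left out. The cytoplasmic pair had 415 probe sets at least 2-fold apart, and 1828 with no filter and 747 with hybridization control scaling. Where a fit kept 1 array in a group, that array is assumed to vary like the other groups. A lone cytoplasmic array adds nothing to the serum estimate of the fit over polyribosome and cytoplasmic RNA.

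List calls were lost, to 0, with an estimated correlation in every comparison that had any. For the averaged serum response 5 lists were called, and 3 with values as deposited, with median centring, with hybridization control scaling, with the filter at the 50th percentile and among probe sets above background, and 1 to 5 with single arrays left out. For the averaged fraction difference 5 were called, and 8 with median centring, 3 with the filter at the 50th percentile, and 3 to 6 with single arrays left out. For the interaction 0 were called, and 11 with values as deposited, 12 with median centring, 11 with hybridization control scaling, and 0 to 2 with single arrays left out. For the replicate contrast 5 were called, and 3 to 7 with single arrays left out. The replicate block moved no other count by over 1.5 times, and among called named genes it ended 1 of 34 calls in the fit over polyribosome and cytoplasmic RNA and 1 of 6 in undertranslated RNA. Of the 34 called genes named in the fit over polyribosome and cytoplasmic RNA, none changed sign, and 31 no longer passed without the starved cytoplasmic array, 31 without the serum cytoplasmic array, 24 without serum polyribosome replicate 2, 21 without starved polyribosome replicate 1, 20 without the variance trend and 19 with no filter. Of the 82 called genes named in the averaged fraction difference, 21 changed sign with hybridization control scaling, 17 with values as deposited and 4 with median centring, and none with the replicate block or the pseudocounts. No paired analysis was possible for the cytoplasmic pair because it has 1 array per group. Array weights, the restriction to probe sets above background and the fit of all 10 arrays were not run for the fit over polyribosome and cytoplasmic RNA.

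With arrays centred on their medians, log2 values in the interaction that changed sign were Fth1 0.89, Dusp1 0.86, Actb 0.14 and Atf4 0.38. With arrays centred on their medians, log2 values in the averaged fraction difference that changed sign were Eef1a1 -1.04, Fos 0.37, Ccl2 0.50, Fth1 0.77, Dusp1 0.74, Actb 1.41, Atf4 1.02, Odc1 0.89 and Junb 0.83. With arrays centred on their medians, log2 values in the averaged serum response that changed sign were Egr1 -0.35, Ccl2 -0.33, Fth1 -0.33 and Dusp1 -0.35. With arrays centred on their medians, log2 values in the serum response over polyribosome and cytoplasmic RNA that changed sign were Egr1 0.079 and Fth1 0.032. With hybridization control scaling, log2 values in the interaction that changed sign were Fth1 0.62, Dusp1 0.60 and Atf4 0.12. With hybridization control scaling, log2 values in the averaged fraction difference that changed sign were 1110032A03Rik 0.17, Col1a1 0.28, Usp25 0.061, Syne4 0.17, Fos 3.15, Ccl2 3.27, Fth1 3.54, Dusp1 3.52, Actb 4.19, Atf4 3.80, Odc1 3.66, Junb 3.61, Klf10 2.54, Tfrc 1.36, Naca 1.60, Shmt2 1.36, Dhps 0.92, Epas1 0.84, Pecam1 1.51, Krt5 0.37, Cdh1 1.96, Klf1 0.97, Hba-a1 1.28, Myod1 1.44, Tnni1 1.19 and Meg3 1.65. With hybridization control scaling, log2 values in the averaged serum response that changed sign were Egr1 -0.66, Ccl2 -0.64, Fth1 -0.64, Dusp1 -0.67, Actb -0.24 and Ptgs2 -0.017. With hybridization control scaling, log2 values in the serum response over polyribosome and cytoplasmic RNA that changed sign were Dusp1 -0.21, Ccl2 -0.21 and Actb -0.22. With values as deposited, log2 values in the interaction that changed sign were Fth1 1.01, Dusp1 0.98, Actb 0.26 and Atf4 0.50. With values as deposited, log2 values in the averaged fraction difference that changed sign were Fos 2.83, Ccl2 2.96, Fth1 3.23, Dusp1 3.21, Actb 3.88, Atf4 3.49, Odc1 3.35, Junb 3.30, Klf10 2.23, Tfrc 1.05, Naca 1.29, Shmt2 1.05, Dhps 0.61, Epas1 0.53, Pecam1 1.20, Krt5 0.056, Cdh1 1.65, Klf1 0.66, Hba-a1 0.97, Myod1 1.12, Tnni1 0.88 and Meg3 1.33. With values as deposited, log2 values in the averaged serum response that changed sign were Egr1 -0.51, Ccl2 -0.49, Fth1 -0.49, Dusp1 -0.52 and Actb -0.091. With values as deposited, log2 values in the serum response over polyribosome and cytoplasmic RNA that changed sign were Egr1 0.011. With single arrays left out, ranges in the averaged serum response that crossed 0 were Egr1 -0.28 to 0.28, Fos -0.41 to 0.009, Fth1 -0.095 to 0.16, Dusp1 -0.10 to 0.12, Atf4 -0.28 to 0.027, Junb -0.58 to 0.31 and Myc -0.094 to 0.56. With single arrays left out, ranges in the averaged fraction difference that crossed 0 were Junb -0.63 to 0.26. With single arrays left out, ranges in the interaction that crossed 0 were Egr1 -0.53 to 0.59, Fos -0.30 to 0.55, Fth1 -0.31 to 0.21, Dusp1 -0.32 to 0.13 and Odc1 -0.23 to 0.28. With single arrays left out, ranges in the serum response over polyribosome and cytoplasmic RNA that crossed 0 were Egr1 -0.38 to 0.25, Dusp1 -0.042 to 0.29 and Fth1 -0.18 to 0.12.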

Other observations

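The tests of macrophage markers were chosen after the result was seen, and those of immediate-early mRNAs, dim arrays and other groupings of the arrays before. In starved cells the Fos probe set had log2 levels of 11.15 in cytoplasmic, 11.09 in undertranslated and 10.67 in polyribosome RNA, Egr1 of 11.84, 10.90 and 11.38, and Egr2 of 12.05, 11.79 and 11.63. After serum Fos stood at 10.80 and Egr1 at 11.67 in cytoplasmic RNA.

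Over polyribosome and cytoplasmic RNA 6 of 9 macrophage markers rose with serum and 3 did not pass (Cd68 0.88, Adgre1 0.99 and Cd53 0.74 log2 units), and some differences were negative in single pools, Cd53 at -0.48 in the cytoplasmic pair and Cd68 at -0.18 in undertranslated RNA. A lower share of fibroblasts would raise the markers of every other cell type alike, and this stays open. Of the members above background on all 6 arrays, 7 macrophage markers had a median of 1.41 (SD 0.301). The 5 skeletal muscle markers, the only other list with enough of them, had one of 0.21 (SD 0.556), 1.20 lower. Skeletal muscle markers thus did not rise alike. That test replaced an earlier one after its values were seen, and 1 list cannot decide for the other cell types. In the fit over the 6 arrays, with all their measured members, the epithelial, endothelial and erythroid lists lay 0.833, 1.077 and 0.957 below the macrophage median. These lists had 1, 4 and 1 members above background on all 6 arrays, too few for the test above. In the cytoplasmic pair, with 1 array per state, the epithelial, endothelial and erythroid lists lay only 0.071, 0.134 and 0.179 below the macrophage median, and skeletal muscle 0.844 below it. These gaps use the markers of the 6-array fit, where 6 epithelial genes had a cytoplasmic median of 0.89. The 5 epithelial genes of the cytoplasmic list test had one of 0.95. A candidate explanation is more macrophages in the serum-treated cultures: the differences of the 8 markers above background on all 3 serum-treated arrays, which leaves out Cd53, had an SD of 0.308 log2 units (0.345 over all 9, 0.651 in the cytoplasmic pair), and Ctss and Cd14 went from log2 levels of 6.90 and 6.46 to 8.64 and 7.56. Variation between dishes stays open, since the lowest serum-treated array exceeded the highest starved one by 0.663 log2 units in mean marker level but 3 arrays against 3 cannot give an exact p under 0.1, and a response of macrophages already present, or of these genes in fibroblasts, was not tested.

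The immediate-early list in starved cells was weighed next. Superinduction by cycloheximide, given to gradient cultures only, would raise them in both gradient pools over cytoplasmic RNA. Their undertranslated minus cytoplasmic median was instead -1.04, at percentile 0.32 of matched random lists, and their polyribosome minus cytoplasmic median was -0.88. Heavy polyribosome loading would put their polyribosome minus undertranslated median high, and it lay at percentile 19.66. Both stay open: 8 members lay higher and 12 lower in polyribosomes with an SD of 0.882, a condition on spread added after the values were seen, and the cytoplasmic comparison rests on 1 starved array.

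The dim undertranslated arrays are a candidate source of the many calls between the fractions, and this stays open. Of probe sets above background on all 8 arrays 64% were called against 47.5% of the rest, a ratio of 1.35. The ratio decides nothing, because the difference itself moves probe sets between these sets: 748 probe sets called higher were below background on all 4 undertranslated arrays.

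Other groupings of the arrays were counted in additive models. For the serum response averaged over the fractions, the real grouping called 5 probe sets in that model and the highest of the other groupings called 0 (1 of 34 gave as many), while the model with 4 groups called 0. At an unadjusted p under 0.05 the real grouping gave 781 and 5 of 34 groupings gave as many, the highest other 1120 (448 among the 8 that part the same-numbered pairs). For polyribosome against undertranslated RNA the real grouping called 4960 and the highest other 0 (1 of 34). For replicate 2 against replicate 1 the real count was 0, so all 32 groupings had to give as many and the count decides nothing. For the 6 polyribosome and cytoplasmic arrays the real grouping called 86 and the highest other 1 (1 of 10), with too few groupings for a share under 0.05. Same-numbered arrays share the labelling, so the real grouping is best set against the 8 that part these pairs, where the highest other counts were 0 for both the serum response and the fraction difference. These are too few for a share under 0.05.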
